A study of Mus musculus with 12 samples.

How the data were processed

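Messenger RNA was profiled on 2-colour arrays in tissues of Sirt6 knockout mice, with wild type tissue of the same kind and age on each array. Per the labels, every array had knockout RNA in Cy5 and wild type RNA in Cy3, so all ratios run the same way and no dye swap was made. Per the labels, knockout RNA was extracted with TRIzol and amplified RNA was labelled; the extraction of the wild type RNA is not given in the sources used here. The authors deposited 1 table of log2 ratios, 38784 probes by 12 arrays; base 2 is inferred from the values (range -8.08 to 9.75), and the scale, centring and normalization behind them are not given in the sources used here. Signal over background is not in the table, so dim spots could not be removed. It lacked 339 to 484 values per array at 29 days and 661 to 10155 at 21 days, where replicate 6 of spleen lacked most.

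The medians of the arrays, in the order 21-day liver 2 and 11, 21-day spleen 6 and 11, 29-day liver 1 and 2, skin 1 and 2, spleen 1 and 2 and thymus 1 and 2, were -0.22, -0.12, 0.21, -0.10, -0.01, 0.01, -0.03, 0.01, -0.03, 0.19, 0.09 and 0.02. Because some exceeded 0.1, each array was centred on its median. GEO's platform annotation gave 1 gene symbol to 22204 probes, several to 0 and none to 16580; all 22204 matched the current gene table (assembly GRCm38.p6) by gene ID. Probes of a gene were averaged per array (4955 genes had more than 1 probe, and the largest number was 95), and unnamed probes were tested on their own, which made 31234 features. Probe positions and the genome build of the design were not used here.

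Groups follow the tissue and age in the labels. Nothing in the labels says that the 29-day arrays of a tissue had separate wild type RNA, or that each array of a group held another knockout animal, so p-values measure the spread between these arrays, which may in part be technical. The replicate numbers of 21-day liver include 1 given by order of deposit. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 12 arrays (lmFit, eBayes, at most 6 residual and 3.57 prior degrees of freedom), and tested each group mean against 0, the mean of the 4 tissues at 29 days, each 29-day tissue against the other 3, and 29 against 21 days in liver and spleen. The tests were two-sided, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. A feature was tested in a group if both arrays of it and of at least 2 further groups had a value. The wild type RNA counted as 1 control, whose own spread is left out.

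Before the data were examined, 39 gene lists were fixed, of which 38 had at least 3 measured members. They were tested with limma's cameraPR on the moderated statistics with a preset correlation of 0.01, adjusted over all lists and the 6 groups. This test sets the genes of a list against all other genes, so the size of its p-values does not reflect the number of animals. The repeat with a correlation estimated from the residuals is given beside it. Results of the fry test are given as counts, and as values for the fasting list in liver alone. The rule for named genes was also fixed then: Sirt6; per group up to 8 genes each way of largest mean change among those with adjusted p under 0.05 and the same sign on both arrays, and the 5 of smallest p where fewer than 5 features passed; up to 10 each way for the mean of the 4 tissues and 6 for the other contrasts; and up to 4 called members of lists that were called or had at least 3 called members. Genes known only by clone or model names were counted and left unnamed. Members of the lists could be named to state values.

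The steps were tested on simulated data over 30871 features with 200 changed genes. The noise was drawn independently for each gene and array, with no dye bias. With 1 spread for all groups, 90% of the genes changed by 2 on the log2 scale and 24% of those changed by 1 were recovered for 29-day liver, with 5 false calls among 119. With the spread of each group as measured, 88% and 14% were recovered for 29-day liver with 0 false calls, and 92% and 60% for 21-day spleen with 1978 false calls among 2131. Alternatives were other centring, scaling and normalization, other filters, each probe on its own, arrays of the same age alone, a replicate block, robust eBayes, a minimum log2 change of 0.58, an adjusted p of 0.1 and leaving out each array in turn. Array quality weights, leaving out the 2 arrays of widest interquartile range and centring on ribosomal and respiratory chain genes were added after seeing the data.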

Results

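The series compared gene expression in tissues of Sirt6 knockout mice with wild type tissue of the same kind. Sirt6 is a chromatin-bound NAD-dependent deacylase, and mice without it stay small and die within weeks of birth. Each of 12 arrays carried labelled RNA of 1 knockout tissue in the red dye (Cy5) and wild type RNA in the green dye (Cy3). There were 6 groups of 2 arrays: liver and spleen at 21 days of age, and liver, skin, spleen and thymus at 29 days. At 21 days the wild type RNA was a pool of 3 littermates; the labels do not say how the wild type RNA of the 29-day arrays was made up. The table gave 38784 probes, of which 28629 to 38445 had a value per array, and named 14654 genes. Values are log2 ratios of knockout over wild type, so a negative value means less RNA in the knockout. No array had the dyes exchanged, so a probe's own dye preference adds to its ratio within a group and cancels between groups only if it is the same in them. The number of arrays limits the precision, and the ratio tests leave out the spread between wild type animals.

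Sirt6 itself was read by 2 probes. Its mean log2 ratio was -0.64 (SE 0.39) in 21-day liver, -1.18 (SE 0.39) in 21-day spleen, -0.23 in 29-day liver, -0.13 in 29-day skin, 0.17 in 29-day spleen and -0.69 in 29-day thymus, and it passed the limma test in none of the 6 groups (lowest adjusted p = 0.103). The probes disagreed on some arrays: on replicate 11 of 21-day spleen one gave -0.91 and the other 0.77. Whether either probe lies in the deleted part of the gene is not given in the sources used here, so these values do not settle the genotype labels. Eif2s3y, a translation factor gene on the Y chromosome, was lower in the knockout channel on all 4 arrays at 21 days, with log2 ratios of -2.87 and -2.98 in liver and -8.00 and -5.04 in spleen. At 29 days it lay between -0.13 and 0.37 on the replicate 1 arrays of all 4 tissues and between 3.35 and 5.08 on the replicate 2 arrays. Kdm5d, another Y-linked gene, gave -0.12 and 0.75 in 29-day liver and -0.45 and 3.03 in 29-day thymus on replicates 1 and 2. In 21-day spleen the Y-linked genes disagreed: Kdm5d was at 0.10 and -2.05, and Uty, a histone demethylase gene, at 0.77 and 0.87. The sex of the animals is not given in the sources used here, so a difference in sex between the channels is not separated from the genotype in the calls of the 21-day groups, nor on the replicate 2 arrays at 29 days, which make up 1 of the 2 arrays behind every 29-day call.

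**Figure D1:**
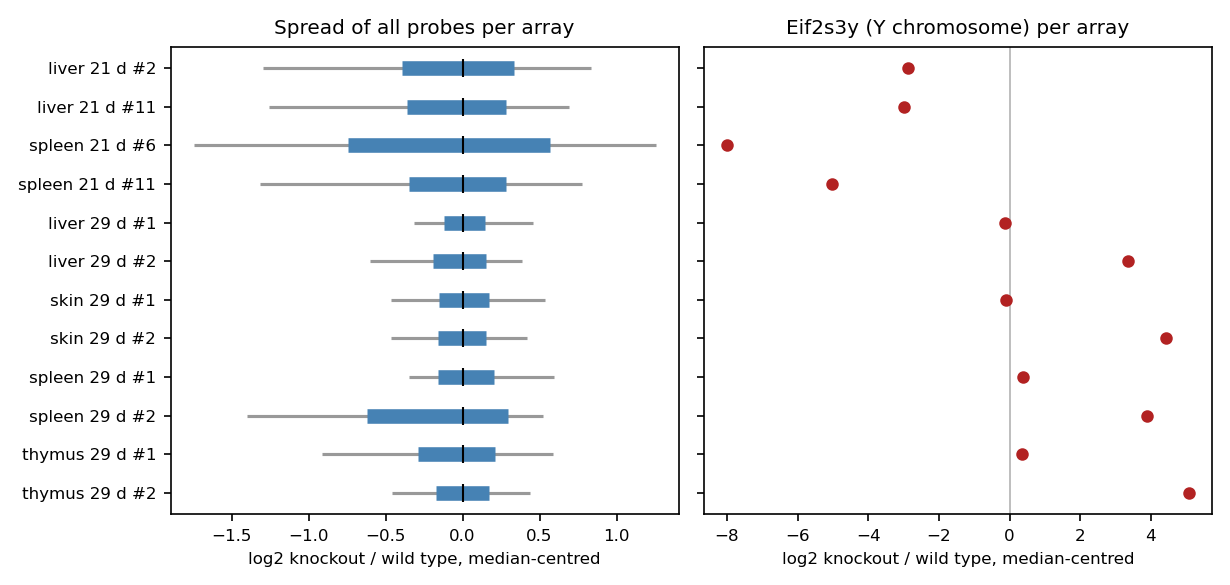
Left, spread of the log2 ratio of knockout over wild type over all probes of each array after centring on the array median (thick bar, between the quartiles of the probes; thin line, 5th to 95th percentile); right, the value of the Y-linked gene Eif2s3y on the same arrays, with # marking the replicate number. Replicate 6 of 21-day spleen and replicate 2 of 29-day spleen had the widest bars between quartiles (1.32 and 0.92), and Eif2s3y ranged from -8.00 to 5.08.

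The arrays differed in spread. The SD of the deposited ratios was 0.72 to 1.14 at 21 days and 0.31 to 0.66 at 29 days, and the widest array of each age was a spleen array. Over all probes the correlation between the arrays of a group was 0.46 in 29-day thymus, 0.36 in 29-day skin, 0.34 in 21-day liver, 0.18 in 29-day liver, 0.12 in 21-day spleen and -0.28 in 29-day spleen (Pearson r across probes, which are not independent replicates). On replicate 2 of 29-day spleen, 74 genes of ribosomal proteins and the respiratory chain had a median of -1.15, and olfactory, vomeronasal and taste receptor genes, which these tissues hardly express, had a median of 0.30; on replicate 1 the medians were 0.31 and -0.03. The joint fit used 1 estimate of the spread per feature for all groups. In simulated data with each group's own spread, 1978 of 2131 calls in 21-day spleen and 72 of 182 in 29-day spleen were false, against 0 of 102 in 29-day liver and 5 of 104 in 21-day liver. The simulated noise was independent between genes and arrays. A bias shared by the arrays of a group could add false calls that these counts do not show. Counts from fits to arrays of the same age stand beside those of the joint fit.

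In 29-day liver, genes of cholesterol synthesis were much lower in the knockout. Idi1, the isopentenyl diphosphate isomerase, fell 19.7-fold (log2 -4.30, SE 0.42, n = 2, limma adjusted p = 0.00871). Msmo1 and Cyp51, demethylases of the sterol ring, fell 8.05-fold and 5.08-fold, and Hmgcs1, which makes HMG-CoA, fell 7.35-fold (adjusted p = 0.00135). Of 17 measured genes of the cholesterol synthesis list, 5 fell over all genes tested and 15 fell when adjusted over the list alone, with none higher in either count. The list's median was -1.24 (list test adjusted p = 1.57e-126, and 7.08e-29 with an estimated correlation). These list p-values compare genes with other genes and do not measure the spread between animals. Fatty acid synthesis followed: Fasn, the fatty acid synthase, fell 3.68-fold and Me1, which supplies NADPH, fell 2.47-fold. The median of the lipogenesis list was -1.03, with 2 of 16 genes lower over all genes tested and 10 adjusted over the list alone (list test adjusted p = 4.64e-44 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, stood at -2.76 (SE 0.43, adjusted p = 0.0784).

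Single genes of liver enzymes and transporters fell as well at 29 days, while the hepatocyte list was not called (median 0.19, adjusted p = 0.469). Sult3a1, a sulfotransferase, fell 13.3-fold (log2 -3.73, SE 0.22, adjusted p = 0.000349), the carboxylesterase gene Ces3b 5.42-fold and the glucuronosyltransferase gene Ugt2b37 4.34-fold; the organic anion transporter gene Slco1a1 fell as well (log2 -2.00). In the list of cytochrome P450 and bile acid genes, Cyp7b1, an oxysterol hydroxylase, fell 3.31-fold and Abcb11, the bile salt export pump, 2.45-fold. That list had a median of -0.46 over 18 genes, with 2 lower over all genes tested and 8 lower and 2 higher adjusted over the list alone (adjusted p = 2.06e-07 with an estimated correlation). Several of these genes belong to families of close relatives, whose transcripts a probe can share. Igf2, the fetal growth factor, rose 6.90-fold (log2 2.79, SE 0.27, adjusted p = 0.00535) and Radx, a DNA replication fork protein, 3.09-fold. The fetal growth list had a median of 0.50 over 10 genes (adjusted p = 3.66e-06 with an estimated correlation), with Igf2 higher over all genes tested and 4 genes adjusted over the list alone. Growth hormone target genes did not pass over all genes tested: Igf1 was at -1.06 (SE 0.28) and Igfals, which carries IGF in blood, at -1.36 (SE 0.22), while Igfbp1, an IGF binding protein induced by fasting, was at 2.23 (SE 0.33).

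The fasting list had a median of 0.31 in 29-day liver, with 0.13 and 0.43 on the arrays (17 genes, 0 called over all genes tested and 2 higher adjusted over the list alone, adjusted p = 0.0155 with an estimated correlation). Acute phase genes had a median of 1.28 over 21 genes, but 2.38 on replicate 1 and 0.16 on replicate 2 (adjusted p = 0.00519 with an estimated correlation, 12 higher adjusted over the list alone, 0 over all genes). Saa2, a serum amyloid, was at 3.48 and 1.06 on these arrays. Macrophage genes (median 0.62) and neutrophil genes (median 0.26) passed the list test with the preset correlation alone (adjusted p = 0.134 and adjusted p = 0.565 with an estimated correlation), and their medians were 0.98 and 0.59 on replicate 1 against 0.15 and -0.01 on replicate 2. Across all features, limma called 32 of 30812 in 29-day liver, 6 higher and 26 lower, of which 19 were named genes. The fit to 29-day arrays alone called 57, including all 32. Scaling, quantile normalization and array quality weights gave many more. Leaving out 1 array at a time gave 12 (without 29-day liver replicate 1) to 59 (without either 21-day spleen array), and centring on ribosomal and respiratory chain genes gave 0 higher and 5 lower.

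**Figure D2:**
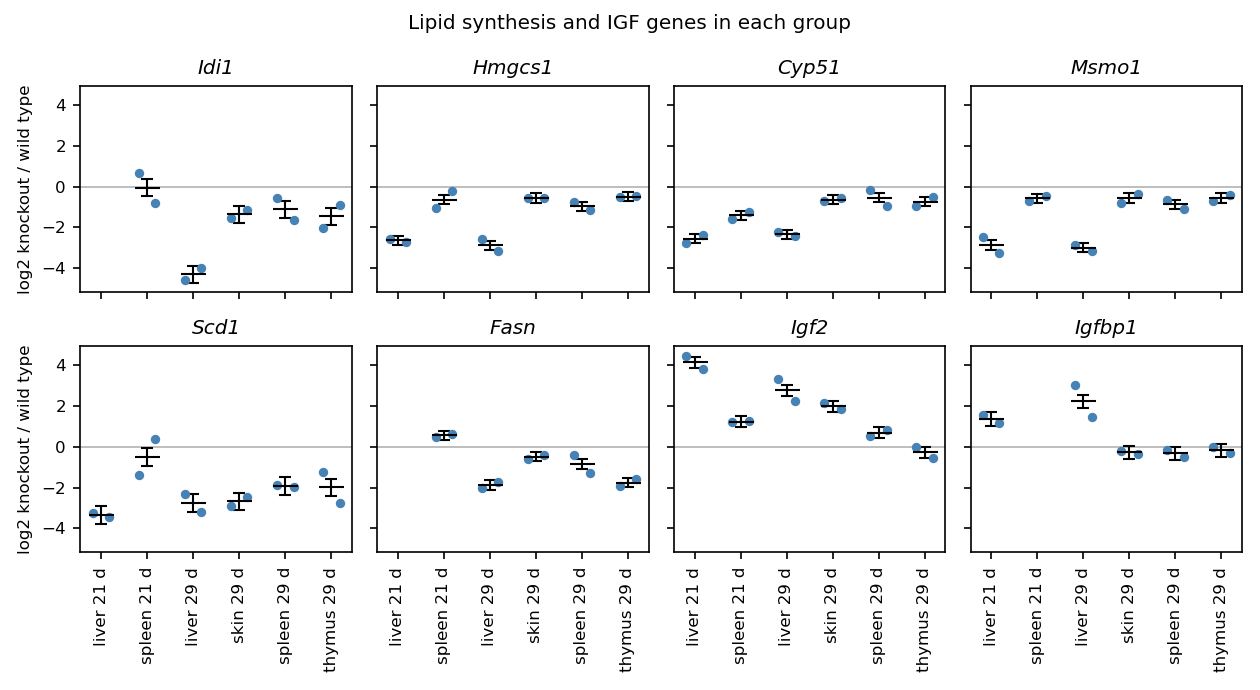
Log2 ratio of knockout over wild type (vertical axis) of 8 genes of cholesterol synthesis (Idi1, Hmgcs1, Cyp51, Msmo1), fatty acid synthesis (Scd1, Fasn) and IGF signalling (Igf2, Igfbp1) in each group; points are the 2 arrays, dashes the mean and bars its SE from the joint fit, and a group without a mark had no value on both arrays. In liver the cholesterol genes lie from -4.30 to -2.34 and Igf2 at 4.16 and 2.79.

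In 21-day liver the same pathways were lower. Msmo1 fell 7.27-fold (log2 -2.86, SE 0.23, adjusted p = 0.00095), Hmgcs1 6.24-fold and Scd1 10.3-fold. Of 15 cholesterol synthesis genes 10 fell, or 13 lower and 1 higher adjusted over the list alone, with a median of -1.66 (adjusted p = 1.41e-06 with an estimated correlation); Fdft1, the squalene synthase gene, was the higher one at 0.49. Of 15 lipogenesis genes 6 fell (7 adjusted over the list alone, median -0.89, adjusted p = 6.7e-05 with an estimated correlation). Igf2 rose 17.9-fold (log2 4.16, SE 0.27, adjusted p = 0.000538), and the fetal liver protein gene Afp 4.79-fold. Igfbp2 rose 4.83-fold and Igfals fell 2.49-fold. Of 10 fetal growth genes 3 rose over all genes tested and 4 adjusted over the list alone (median 0.44, adjusted p = 0.00273 with an estimated correlation), and of 16 fasting genes 2 and 4 rose in these counts (median 0.58, adjusted p = 0.0409 with an estimated correlation). Cpt1a, which carries fatty acids into mitochondria, was among the fasting genes that rose (log2 0.95).

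Clock genes had a median of 0.40 in 21-day liver (16 genes, 2 higher over all genes tested, 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0207 with an estimated correlation), led by Per2, a repressor of the clock, which rose 2.25-fold. Aldh1a1, a retinaldehyde dehydrogenase, fell 15.4-fold and the club cell and liver enzyme gene Cyp2f2 5.63-fold. The P450 list (median -0.44, 1 higher and 4 lower) passed with the preset correlation alone (adjusted p = 0.599 with an estimated correlation), as did glucocorticoid-induced genes (median 0.28, adjusted p = 0.708 with an estimated correlation) and the growth hormone and IGF list (mean 0.47, adjusted p = 0.186 with an estimated correlation), whose median of 0.0038 turned to -0.17 without centring, -0.01 with scaling and -0.12 with centring on ribosomal and respiratory chain genes, while the list test still placed it higher (adjusted p = 0.00206, 0.136 and 0.0013). Members of the growth hormone and IGF list went both ways. Igf2, also in the fetal growth list, was at 4.16 and Igfbp2 at 2.27, but Igf1 was at -0.785 and Igfals at -1.32. In all, 738 of 29093 features were called, 130 higher and 608 lower. Without centring they were 74 and 1203. The fit to the 21-day arrays alone called 0, with 1404 features at an unadjusted p under 0.05, and 41 of the 337 named genes called (12.2%) were olfactory, vomeronasal or taste receptors, which made up 6.77% of the named genes tested.

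Of the features called in 29-day liver, 30 had values at 21 days and 29 of these had the same direction there. Called at both ages were 6 higher and 21 lower features. All arrays share 1 dye orientation and 1 spread estimate per feature, so no value is given for the sharing that would arise without an effect of genotype. The test of the age difference in liver called 4 of 29043 features, all 4 unnamed probes, higher at 29 days by 2.25 to 3.42 (adjusted p = 0.0404 to 0.0461). No named gene passed: Slco1a1 was lower by -1.34 (SE 0.26, adjusted p = 0.171), Hsd3b5, a steroid dehydrogenase gene, by -1.64 (adjusted p = 0.156), and Ccl20, a chemokine gene, higher by 2.13 (adjusted p = 0.0696). The 21-day and 29-day arrays came from different sets, so age and array set cannot be told apart, and Eif2s3y differed between the ages as well, at -2.87 and -2.98 against -0.13 and 3.35 in liver. With arrays scaled to the same spread 1 feature was higher and 14 lower, and leaving out 1 array gave 0 (without 29-day liver replicate 2, among others) to 515 (without 21-day liver replicate 11).

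In 29-day skin, Epyc, an extracellular matrix proteoglycan of cartilage, rose 5.58-fold (log2 2.48, SE 0.25, n = 2, adjusted p = 0.031). Il22ra2, the soluble IL-22 receptor, rose 3.15-fold, Cacng1, a calcium channel subunit of muscle, 2.82-fold and Gpr1, a chemerin receptor, 2.55-fold. Akr1c14, a hydroxysteroid dehydrogenase, fell 3.63-fold, Npr3, the natriuretic peptide clearance receptor, 3.07-fold and the opsin gene Opn3 2.36-fold, each at adjusted p = 0.0464. Glucocorticoid-induced genes had a median of 0.69 over 14 genes, with 0 called over all genes tested and 7 higher adjusted over the list alone (adjusted p = 0.000673 with an estimated correlation); Fkbp5, a chaperone of the glucocorticoid receptor, was at 1.54 and Ddit4, an inhibitor of mTOR, at 1.67. Epidermal keratinocyte markers had a median of 0.28 (13 genes, 2 higher adjusted over the list alone, adjusted p = 0.000105 with an estimated correlation). Lor, the cornified envelope protein loricrin, was at 0.96, and the lowest member, Dsc3, at -0.28. Hair genes (median 0.13, adjusted p = 0.0283) and clock genes (median 0.11, adjusted p = 0.0119) also passed with an estimated correlation.

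The lipogenesis list was lower in skin (median -0.28 over 16 genes, adjusted p = 7.74e-06 with an estimated correlation, 0 called over all genes tested and 1 adjusted over the list alone), led by Scd1 at -2.68 (SE 0.43, adjusted p = 0.125). Further lists passed with the preset correlation alone. Lower were cholesterol synthesis (median -0.35, adjusted p = 0.0788 with an estimated correlation), adipocyte genes (median -0.51, adjusted p = 0.29), extracellular matrix genes (median -0.42, adjusted p = 0.181), MHC class II genes (median -0.16, adjusted p = 0.563) and exocrine pancreas genes (median -0.30, adjusted p = 0.428). Higher were skeletal muscle genes (median 0.36, adjusted p = 0.0568), ribosomal protein genes (median 0.62, adjusted p = 0.331) and p53 targets (median 0.09, adjusted p = 0.186). Lep, the fat hormone leptin, stood at -1.48 and Igf1 at -1.17 (SE 0.28). Centring on ribosomal and respiratory chain genes, which moved the skin arrays by 0.45 and 0.23, turned the medians of the epidermal (-0.06), hair (-0.21), clock (-0.23) and p53 (-0.25) lists below 0; against other genes the list test still placed them higher, with adjusted p = 0.000383, 0.0598, 0.0217 and 0.0949. Of 30810 features 5 were called higher and 7 lower. With a replicate block only 1 feature was called. The fit to 29-day arrays called 17 and 26, including all 12, and quantile normalization 149 and 357. The count also depended strongly on which array was left out.

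In 29-day spleen no feature of 30783 was called by limma (1015 at an unadjusted p under 0.05; 0 also in the fit to 29-day arrays). The lists of B cell, MHC class II and cytotoxic genes were lower. B cell genes had a median of -0.68 over 16 genes, with 0 called over all genes tested and 8 lower adjusted over the list alone (adjusted p = 0.0332 with an estimated correlation), and their medians were -0.55 and -0.80 on the arrays. Vpreb3, a pre-B cell receptor component, was at -1.33 (SE 0.32), and Cd79b, a signalling chain of the B cell receptor, at -1.17 (SE 0.39). MHC class II genes had a median of -0.65 (6 genes, 4 lower adjusted over the list alone, adjusted p = 0.00519 with an estimated correlation) and natural killer and cytotoxic genes one of -0.25 (12 genes, adjusted p = 0.00214). In the cytotoxic list Ccl5 was the only gene that passed when adjusted over the list alone, and Gzmb, Il2rb and Eomes lay above 0. Ccl5, a chemokine of cytotoxic lymphocytes, was at -1.13 (SE 0.16, adjusted p = 0.307) and Kmo, an enzyme of tryptophan breakdown, at -1.20 (SE 0.16, adjusted p = 0.232). Slfn4, an interferon-induced gene of myeloid cells, was at 1.16 and Stfa3, a stefin of neutrophils, at 2.55 (adjusted p = 1.00 for both).

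Transcripts of other organs differed in the spleen samples too. Hepatocyte genes had a median of -0.81 in 29-day spleen (15 genes, 8 lower adjusted over the list alone, adjusted p = 2.13e-06 with an estimated correlation), with albumin (Alb) at -2.10 (SE 0.36) and the apolipoprotein gene Apoa1 at -1.81. Exocrine pancreas genes had a median of 0.72 (9 genes, 7 higher adjusted over the list alone, adjusted p = 0.000873 with an estimated correlation) but 0.08 on replicate 1 and 1.07 on replicate 2. Adipocyte genes had a median of -0.23 and a mean of -0.66 (adjusted p = 0.541 with an estimated correlation), with Adipoq, the fat hormone adiponectin, at -2.26 and Car3, a carbonic anhydrase of fat and muscle, at -3.12. Lipogenesis genes had a median of -0.24 (adjusted p = 0.00519 with an estimated correlation), with Scd1 at -1.92, and cholesterol synthesis genes one of -0.39 (adjusted p = 0.0764).

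For the erythroid, cell cycle, respiratory chain and ribosomal protein lists, the 29-day spleen arrays had opposite signs. Erythroid genes were at 0.59 on replicate 1 and -2.36 on replicate 2, cell cycle genes at 0.42 and -1.76, respiratory chain genes at 0.25 and -1.28, ribosomal protein genes at 0.36 and -1.01. Their calls as lower in the mean (adjusted p = 0.599, 0.622, 0.565 and 0.842 with an estimated correlation) turned to higher without replicate 2. T cell genes (median -0.31, adjusted p = 0.637), base excision repair genes (-0.22, adjusted p = 0.627), P450 genes (-0.26, adjusted p = 0.258), acute phase genes (-0.41, adjusted p = 0.859) and glucocorticoid-induced genes (0.28, adjusted p = 0.708) passed with the preset correlation alone. Centring on ribosomal and respiratory chain genes turned the medians of the T cell (0.10), cytotoxic (0.17), lipogenesis (0.18), cholesterol synthesis (0.03), P450 (0.16), adipocyte (0.19), repair (0.20), acute phase (0.01), NF-kB (0.26) and ribosomal (0.11) lists above 0, and left those of the B cell, MHC class II and hepatocyte lists below 0. The list test, which compares a list with other genes, still placed the 10 lists with turned medians lower, but no longer passed for repair genes and NF-kB targets (adjusted p = 0.0623 and 0.339); for the other 8 the highest adjusted p was 0.037. Without replicate 1 of 29-day spleen 316 features were called, and without replicate 2 none.

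In the 21-day spleen samples, exocrine pancreas genes, transcripts of another organ, were lower together. The source of these transcripts in the spleen samples was not tested. Cel, the bile salt-activated lipase, fell 5.47-fold (log2 -2.45, SE 0.32, n = 2, adjusted p = 0.00988), the trypsin gene Try4 4.91-fold, the elastase gene Cela3b 4.17-fold and the chymotrypsinogen gene Ctrb1 3.82-fold. Of 8 measured, 5 fell over all genes tested and 6 adjusted over the list alone (median -1.74, adjusted p = 0.00137 with an estimated correlation). Erythroid genes (median -1.18), cell cycle genes (median -1.12) and respiratory chain genes (median -0.74) passed as lower with the preset correlation alone (adjusted p = 0.695, 0.776 and 0.816 with an estimated correlation). On replicates 6 and 11 their medians were -1.30 and -1.62, -1.35 and -0.92, and -1.15 and -0.21, and abundant genes lay below the receptor genes by -1.12 on replicate 6, against 0.01 on replicate 11. Hrc, a calcium-binding protein of muscle, rose 6.24-fold, and Isl1, a transcription factor of motor neurons and islets, fell by 3.70 on the log2 scale. Of 23146 features 262 were called higher and 695 lower, and 45 of the 472 named genes called (9.53%) were olfactory, vomeronasal or taste receptors, which made up 6.10% of the named genes tested. The fit to 21-day arrays called 0 (2321 at an unadjusted p under 0.05), quantile normalization 1 and 11, centring on ribosomal and respiratory chain genes 6 and 17, and leaving out 1 array gave 182 (without either 29-day skin array) to 6422 (without 21-day spleen replicate 11).

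Between the ages, Try4 and Ctrb1 were higher at 29 than at 21 days in spleen, by 2.98 (SE 0.31, adjusted p = 0.035) and 2.63 (SE 0.27, adjusted p = 0.0253) on the log2 scale. Isl1, Vmn1r183 (a pheromone receptor gene), Cyp4a12a (a fatty acid hydroxylase) and Nr2e1 (a nuclear receptor of neural stem cells) were higher by 4.07, 4.22, 2.95 and 2.07, and Hrc was lower by -2.45. Ccl5 was lower by -1.56 (SE 0.22, adjusted p = 0.0711). The exocrine pancreas list, called lower at 21 and higher at 29 days, differed by a median of 2.41 (8 genes), with medians of 0.08 and 1.07 on the 29-day arrays. Whether the pancreas transcripts, Try4 and Ctrb1 among them, arose in the spleen itself was not tested. The test called 19 features higher and 1 lower of 23086; age and array set cannot be told apart here either, and Eif2s3y was at -8.00 and -5.04 against 0.37 and 3.88. Leaving out 1 array gave 0 (without 29-day liver replicate 1, among others) to 2593 (without 21-day spleen replicate 11), and array quality weights gave 0.

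In 29-day thymus the 4 called genes were all lower. Mb, the oxygen store myoglobin, fell 7.01-fold (log2 -2.81, SE 0.22, n = 2, adjusted p = 0.00674). Myl4, an atrial myosin light chain, fell 4.92-fold, Ckmt2, a mitochondrial creatine kinase of muscle, 3.87-fold and Corin, a heart protease that activates atrial natriuretic peptide, 3.04-fold (adjusted p = 0.0486 for both). Myl7, the other atrial light chain, was at -2.64 (SE 0.31, adjusted p = 0.0608). The skeletal muscle list, which holds Mb, had a median of -0.15 and a mean of -0.39 (17 genes, 1 lower over all genes tested and 3 adjusted over the list alone, adjusted p = 0.0321 with an estimated correlation). Lipogenesis genes had a median of -0.30 (16 genes, 2 lower adjusted over the list alone, adjusted p = 0.000179 with an estimated correlation), with Fasn at -1.76 (SE 0.23) and Scd1 at -1.99 (SE 0.43). Txnip, an inhibitor of glucose uptake, was at 1.14 (adjusted p = 0.693), Agt, the angiotensin precursor, at 1.18 (adjusted p = 0.598) and Glul, the glutamine synthetase, at 1.05 (adjusted p = 0.794).

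Cell cycle genes had a thymus median of -0.87 over 28 genes, -1.47 on replicate 1 and -0.27 on replicate 2, and passed with the preset correlation alone (adjusted p = 0.29 with an estimated correlation). The same held for immature thymocyte genes (median -0.36, adjusted p = 0.247), base excision repair genes (-0.34, adjusted p = 0.292), interferon-induced genes (-0.21, adjusted p = 0.462), glycolysis genes (-0.29, adjusted p = 0.79) and cholesterol synthesis genes (-0.46, adjusted p = 0.102), all lower, and for B cell genes (0.33, but 0.68 and -0.03 on the arrays, adjusted p = 0.565), glucocorticoid-induced genes (0.50, adjusted p = 0.301) and fasting genes (0.24, adjusted p = 0.525), all higher. Of 30806 thymus features 0 were called higher and 4 lower. Centring on ribosomal and respiratory chain genes gave 0 and a replicate block 1, while scaling, quantile normalization and array quality weights gave more. The fit to 29-day arrays called 3 and 21, including all 4, and leaving out 1 array gave 0 (without thymus replicate 1) to 13 (without either 21-day spleen array).

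The mean over the 4 tissues at 29 days asks which genes differed on average. The fit took the arrays of different tissues as independent. Eif2s3y split by replicate number in all 4 tissues, so tissues of the same number may share animals. In that case the p-values here count arrays rather than animals. Scd1 fell 5.05-fold (log2 -2.34, SE 0.22, adjusted p = 0.00727) and lay between -2.76 and -1.92 in every tissue. Idi1 fell 4.16-fold, Msmo1 2.38-fold, Fasn 2.36-fold, Hmgcs1 2.34-fold and Cyp51 2.09-fold, and Akr1c14 and Kmo fell 1.82-fold and 1.52-fold. Liver weighed most in the cholesterol genes: Msmo1 was at -3.01 in liver and between -0.87 and -0.56 in the other tissues, Hmgcs1 at -2.88 and between -0.97 and -0.50, Cyp51 at -2.35 and between -0.74 and -0.54, and Idi1 at -4.30 and between -1.46 and -1.12. Igf2 rose 2.47-fold (adjusted p = 0.0122), with 2.79 in liver, 2.00 in skin, 0.70 in spleen and -0.27 in thymus, and Epyc 1.97-fold. Fkbp5 was at 0.98 (SE 0.14, adjusted p = 0.0773) and Txnip at 0.76 (adjusted p = 0.126). Limma called 15 of 30641 features, 3 higher and 12 lower; the fit to 29-day arrays called 33, including all 15, quantile normalization 942, centring on ribosomal and respiratory chain genes 2, and leaving out 1 array gave 1 (without skin replicate 2) to 58 (without spleen replicate 1).

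Tested against the mean of the other 3 tissues, 7 named genes were lower in 29-day liver. Sult3a1 differed by -3.98 (SE 0.26, adjusted p = 0.00142), Ces3b by -2.50, Ugt2b37 by -2.36, Msmo1 by -2.35, Hmgcs1 by -2.20 and Slco1a1 by -2.09. Mb (-2.69, SE 0.25, adjusted p = 0.0358), Myl4 (-2.24) and Myoz2, a sarcomere protein gene (-1.87), were lower in thymus than in the other tissues. The counts were 1 higher and 10 lower in liver, 0 and 3 in thymus, and 0 in both skin and spleen (751 and 549 features at an unadjusted p under 0.05). With a replicate block 1 feature was specific to liver and 0 to thymus. Centring on ribosomal and respiratory chain genes gave 0 in liver and 0 in thymus, while scaling and quantile normalization raised both counts. Epyc in skin (2.00, adjusted p = 0.32) and Apoa1 in spleen (-2.13, adjusted p = 0.868) were among the genes of smallest p that did not pass. Scaling and quantile normalization raised the skin count to 105 and 171; leaving out 1 array gave 1 (without liver replicate 1, among others) to 30 (without either 21-day spleen array) in liver, 0 to 1 in skin, 0 to 50 in spleen (50 without spleen replicate 1) and 0 to 8 in thymus (8 without either 21-day spleen array, 0 without either 21-day liver array, among others).

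NF-kB target genes were among the lists fixed before the data were examined, because SIRT6 is known to bind the NF-kB subunit RelA. The list, with 28 genes measured at 29 days, had a median of 0.16 in 29-day liver (adjusted p = 2.28e-05; adjusted p = 0.29 with an estimated correlation), with 0.22 on replicate 1 and 0.01 on replicate 2. It was at -0.09 in 29-day skin (adjusted p = 0.0464, and 0.751 with an estimated correlation) and at -0.16 in 29-day spleen (adjusted p = 0.0428, and 0.75 with an estimated correlation); the spleen median turned to 0.26 with centring on ribosomal and respiratory chain genes and to 0.15 without replicate 2 (adjusted p = 0.339 and 0.93). In 29-day thymus (-0.12, adjusted p = 0.101), 21-day liver (0.05, adjusted p = 0.955) and 21-day spleen (0.12, adjusted p = 0.206) it was not called. No member passed over all genes tested at 29 days. Adjusted over the list alone, skin had Nfkbia, the NF-kB inhibitor, higher at 0.93 and the dendritic cell marker Cd83 and Ccl5 lower at -0.73 and -0.75, and spleen had 3 lower. In 21-day liver Ccl20 (-1.98) and Mmp9, a matrix metalloproteinase (-1.86), fell, and 2 genes were higher and 3 lower adjusted over the list alone. In 21-day spleen the chemokine gene Cxcl2 (1.63) and Junb, a subunit of AP-1 (1.63), were higher adjusted over the list alone, and 0 over all genes tested.

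**Figure D3:**
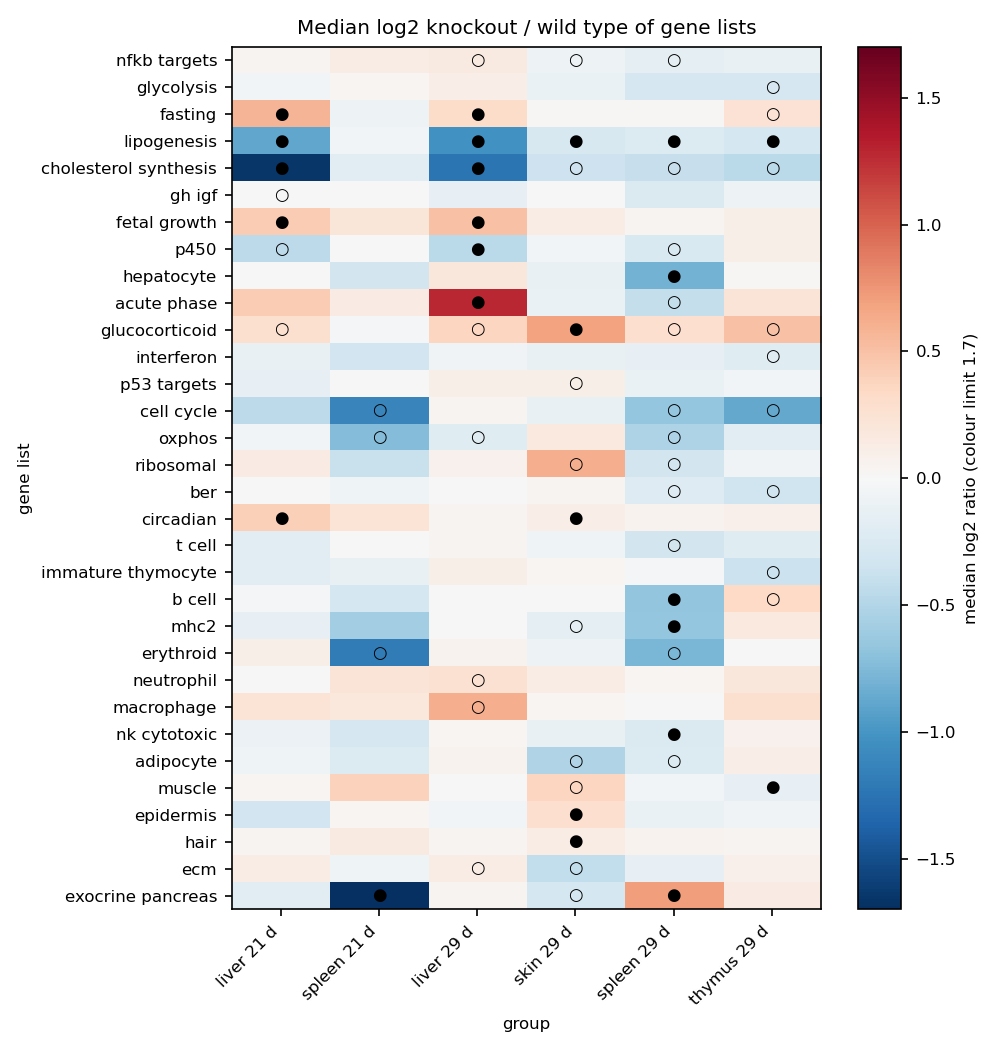
Median log2 ratio of knockout over wild type (colour) of the gene lists (rows) with a call in at least 1 of the 6 groups (columns); filled circles mark calls that held with an estimated correlation between genes, open circles calls with the preset correlation alone, and colours stop at 1.7. Of 67 calls, 25 held, among them the lipogenesis list in 5 groups and cholesterol synthesis in both liver groups.

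Over the 6 groups, 227 list tests were made on 38 lists. With the preset correlation 25 lists were called higher and 42 lower, and 25 of the 67 calls held with an estimated correlation. Fry, which asks only whether a list's genes move one way on balance, was run on features with a value on all 12 arrays. It called 12, of which 10 were among the 67 in the same direction. By group, fry called 5 lists in 21-day liver, 2 in 21-day spleen, 3 in 29-day liver, 1 in skin, 1 in 29-day spleen and 0 in thymus. Respiratory chain genes (median -0.20, adjusted p = 0.859 with an estimated correlation), glucocorticoid-induced genes (0.36, adjusted p = 0.0647) and extracellular matrix genes (0.13, but 0.41 and -0.03 on the arrays, adjusted p = 0.637) were the other 29-day liver lists called with the preset correlation alone.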

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

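The tests below of sex, dye effects, a fasting-like state, signal-dependent bias and exchanged channels were chosen after the results were seen; the test of the second heart list was written before its values were seen, though after the called thymus genes were known. The rules by which the dye tests are read were also changed after their values were seen. The liver test was read first as evidence against a dye effect, later as leaving it open, then as evidence against an effect that is the same in every tissue. It is read here as leaving a dye effect open. The features specific to a tissue and the age differences differ between groups by a test of the difference itself, and the lists at the end were called in opposite directions; the disagreement between the 29-day spleen arrays lies within a group and no such test covers it.

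Cholesterol synthesis genes lay lower in 29-day liver than in the other 3 tissues, with Msmo1 at -2.35 and Hmgcs1 at -2.20 among the 11 features that differed. The tables argue against a sex difference between the animals of a pair as the whole cause, since the list median on replicate 1, where Eif2s3y was at -0.13, was 0.916 of that on replicate 2 (-1.09 and -1.19). A dye effect of the probes that is the same in every tissue would not by itself make liver differ from the other tissues. The list median differed by -0.75 between liver and these (limma list test adjusted p = 1.69e-12 with an estimated correlation). That difference is what flagged these genes, so it is no independent test. The list was shifted in all 3 other tissues with the preset correlation alone, and a probe without signal there would show no dye effect. A dye effect was therefore not settled. An effect that varies with signal was not tested, as signal is not in the values used here. A liver state like that of fasting remains open as a hypothesis, since the fasting list had medians of 0.58 and 0.31 at 21 and 29 days (adjusted p = 0.0409 and 0.0155 with an estimated correlation, but 0.164 and 0.671 by fry), the latter with 0.13 and 0.43 on the arrays and 0.13 to 0.55 over the settings. Food intake is not given in the sources used here, and a direct effect of the genotype was not tested apart from it.

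Heart and muscle genes lay lower in 29-day thymus than in the other tissues, with 3 features called: Mb at -2.69, Myl4 at -2.24 and Myoz2 at -1.87. A list of 22 heart genes, written after the called genes were seen, had a thymus median of -1.62. Heart tissue in the wild type thymus RNA may account for the pattern: a second list of 11 heart genes had a median of -0.31 (unadjusted list test p = 0.00156 with the preset correlation, 8 lower), against -0.03 for 8 fast-fibre muscle genes. That median lay close to the bound of -0.3 set for it, the list was at -0.31 in 21-day liver and 21-day spleen as well (not passed in either), 3 of its genes are also in the first list, and Myl2 and Myl3, abundant in the heart ventricle, were at 0.46 and -0.31 while the atrial Myl7 was at -2.64. The second list differed from the other tissues by -0.49 (adjusted p = 2.69e-05 with an estimated correlation), in part through skin, where its median was 0.21, but a dye effect of the probes and the genotype cannot be told apart for these genes, since the list was shifted in only 1 of the 3 other tissues and a probe without signal there would show none; a change of the thymus itself was not tested.

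The arrays of 29-day spleen disagreed, with a correlation of -0.28 across probes. The difference between abundant and hardly expressed genes was 0.35 on replicate 1 and -1.45 on replicate 2, a gap of -1.80, so a signal-dependent bias between the dyes on replicate 2 is a candidate explanation. Whether the channels were exchanged on replicate 2 was not settled. Of 44 features called in other 29-day tissues, 30 had the same sign there (68.2%, interval 52.4 to 81.4), and 37 of 44 on replicate 1. The interval takes co-regulated features as independent, and a dye bias of the probes would keep its sign on an exchanged array. An earlier form of this test, on 104 features large on both spleen arrays, gave 48 of the same sign (46.2%). The Y-linked genes Eif2s3y, Kdm5d and Uty were at 3.876, 1.555 and 0.674 on spleen replicate 2, against 0.367, 0.354 and 0.026 on replicate 1. On replicate 2 of liver, skin and thymus they were above 0 as well. If arrays of the same replicate number share animals, these values argue against an exchange, but the labels do not say that they do. A difference between the animals was not tested apart from these.

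The other features specific to 29-day liver were Slco1a1 at -2.09, Ugt2b37 at -2.36, Ces3b at -2.50 and Sult3a1 at -3.98. Between 21 and 29 days, 4 features differed in liver and 20 in spleen, among the latter Vmn1r183 at 4.22, Isl1 at 4.07, Try4 at 2.98, Cyp4a12a at 2.95, Ctrb1 at 2.63, Nr2e1 at 2.07 and Hrc at -2.45.

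The last results are gene lists that were called in opposite directions in 2 groups. A test of the difference would restate that choice, so the differences of the medians are given as values. Those with both calls held with an estimated correlation were exocrine pancreas genes, higher in 29-day spleen (0.08 and 1.07 on the arrays) than in 21-day spleen by 2.46. In the others at least 1 of the calls was lost with an estimated correlation. Exocrine pancreas genes were higher in 29-day spleen than in skin by 1.02 (adjusted p = 0.428 in skin with an estimated correlation). Acute phase genes were higher in 29-day liver (2.38 and 0.16) than in 29-day spleen (-0.11 and -1.14) by 1.69 (adjusted p = 0.859 in spleen with an estimated correlation). Members ran both ways in spleen: Fgg, Apcs and Fgb were at -1.43, -1.14 and -1.10, and Saa3, Serpina3n and Mt1 at 0.71, 0.46 and 0.46. The hepatocyte list was lower in 29-day spleen as well, and the acute phase list was not tested apart from it. B cell genes were higher in thymus (0.68 and -0.03) than in spleen by 1.01 (adjusted p = 0.565 in thymus). Extracellular matrix genes were higher in liver (0.41 and -0.03) than in skin by 0.55 (adjusted p = 0.637 and 0.181 with an estimated correlation), and muscle genes higher in skin than in thymus by 0.51 (adjusted p = 0.0568 in skin). NF-kB targets were higher in liver (0.22 and 0.01) than in skin by 0.24 and than in spleen (0.15 and -0.16) by 0.31 (adjusted p = 0.29, 0.751 and 0.75 with an estimated correlation). Ribosomal protein genes were higher in skin than in spleen (0.36 and -1.01) by 0.93 (adjusted p = 0.331 and 0.842 with an estimated correlation), and the spleen direction turned without replicate 2.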

How the results depend on the processing

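Array quality weights, leaving out the 2 arrays of widest interquartile range (replicate 6 of 21-day spleen and replicate 2 of 29-day spleen) and centring on ribosomal and respiratory chain genes were chosen after seeing the data; the other alternatives were fixed before. No named gene reversed, but many lost their call: over pairs of a called gene and a setting, the call was kept and lost in 539 and 160 for 21-day liver, 298 and 227 for 21-day spleen, 254 and 64 for 29-day liver, 67 and 93 for skin, 53 and 37 for thymus, 147 and 80 for the mean of 4 tissues, 85 and 52 specific to liver, 27 and 41 specific to thymus, and 60 and 92 for age in spleen. Counts below are of 21-day liver, 21-day spleen, 29-day liver, skin, 29-day spleen, thymus, the mean of 4 tissues, features specific to liver, skin, spleen and thymus, and the age difference in liver and spleen, 738, 957, 32, 12, 0, 4, 15, 11, 0, 0, 3, 4 and 20 as reported; counts not given were within 1.5 times these. Without centring they were 1277 for 21-day liver, 6 for skin, 1 for 29-day spleen, 0 specific to thymus and 23 for age in liver. With scaling the counts were 147, 10, 285, 427, 0, 28, 528, 153, 105, 2, 19, 15 and 2, and with quantile normalization 73, 12, 424, 506, 13, 57, 942, 159, 171, 14, 21, 0 and 0. Features with a value on all 12 arrays gave 402 for 21-day liver, 16 for 29-day liver, 3 for skin, 1 for thymus, 7 for the mean, 1 specific to thymus, and 0 and 2 for age in liver and spleen. With no filter thymus gave 2; each probe on its own gave 6 for skin, 2 for thymus and 0 specific to thymus. Arrays of the same age gave 0 and 0 at 21 days, 57 for liver, 43 for skin, 24 for thymus, 33 for the mean, 20 specific to liver and 10 to thymus. An adjusted p under 0.1 gave 1800, 3024, 57, 27, 1, 12 and 33 for the first 7 counts, 8 specific to thymus, and 24 and 45 for age. Array weights gave 428, 0, 224, 569, 0, 185, 78, 71, 41, 0, 42, 71 and 0; without the 2 arrays of widest interquartile range they were 3565, 2585, 73, 33, 4, 15, 28, 20, 0, 1, 0, 100 and 1098; centring on ribosomal and respiratory chain genes gave 128, 23, 5, 1, 0, 0, 2, 0, 0, 0, 0, 0 and 0. Robust eBayes and a minimum log2 change of 0.58 moved no count by more than 1.5 times. Against 67 list calls, 25 were made with an estimated correlation and 12 by fry, of which 10 were among the 67 in the same direction. Of 23 settings, the call was kept in 7 for base excision repair, 8 for NF-kB targets and 13 for acute phase genes in 29-day spleen, in 10 for NF-kB targets, 11 for MHC class II and 15 for p53 targets in skin, and in 14 for P450 genes in 21-day liver. The other 60 calls were kept in at least 19. Many settings leave out an array of another group, so a high count is a weak check. Erythroid and cell cycle genes in 29-day spleen kept their call in 20 and 21, though their direction turned without replicate 2. The cause of these changes was not tested.

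The labels do not say that replicates 1 and 2 of the 29-day tissues pair. Replicate differences correlated between liver and spleen (r = 0.413) and skin and spleen (r = 0.222), and negatively between spleen and thymus (r = -0.209). In the other pairs of tissues r was -0.011 to 0.028, probes not being independent. Eif2s3y, by contrast, split by number in all 4 tissues. With a replicate block the counts were 402 and 404 at 21 days, 1 for skin, 1 for thymus, 1 specific to liver, 0 specific to thymus, and 0 and 0 for age; the block spends degrees of freedom, and a call lost there is not shown to be a weaker effect.

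Leaving out each array in turn, with the lone array of a group assumed to vary like the other groups, gave 288 to 1942, 182 to 6422, 12 to 59, 1 to 35, 0 to 316, 0 to 13, 1 to 58, 1 to 30, 0 to 1, 0 to 50, 0 to 8, 0 to 515 and 0 to 2593 in the order above, and 59 to 71 list calls. Signal over background is not in the values used here, so dim spots stay among the features.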

Other observations

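Further lists fixed before the data were examined passed in few groups. Glycolysis genes, a pathway SIRT6 is known to repress, had medians of -0.05 in 21-day liver, 0.03 in 21-day spleen, 0.11 in 29-day liver, -0.11 in skin, -0.29 in 29-day spleen and -0.29 in thymus, and were called lower in thymus alone with the preset correlation (adjusted p = 0.0278; adjusted p = 0.79 with an estimated correlation). Hypoxia response genes had medians of 0.21, -0.30, 0.17, -0.02, -0.06 and -0.05 in the same order and were called in no group (lowest adjusted p = 0.0676). Hepatocyte genes, lower in 29-day spleen, had a median of 0.19 in 29-day liver (adjusted p = 0.469) and 0.02 in thymus (adjusted p = 0.741). In 21-day spleen, albumin (Alb) and Apoa1 fell (log2 -1.94 and -1.55, SE 0.36 and 0.35, adjusted p = 0.0277 and 0.0434), while the hepatocyte list was not called there (median -0.32, adjusted p = 0.121).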
